A study of Xenopus tropicalis with 15 samples.

How the data were processed

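Total peripheral blood cells of wild-type Xenopus tropicalis were collected from the heart with EDTA, washed, and either harvested fresh or cultured for 1.5 h or 4.0 h in diluted IMDM medium with fetal calf serum, without or with 1 ng/mL recombinant X. tropicalis EPO made in E. coli, per the labels' protocols. After a guanidine and phenol extraction of total RNA, 3' RNA-seq libraries were made with Lasy-Seq v1.1, per the labels. There are 15 samples in 5 groups of 3, which the labels call biological replicates without saying which animals they came from, so the p-values measure the spread between these samples.

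The deposited table holds raw whole-number counts for 26531 genes, 1 column per sample. The submitters' processing notes name fastp 0.21.0, BWA 0.7.17-r1188, Salmon without a version and R 4.3.2. The role and order of these tools, the genome build, the annotation and the handling of strand are not given in the sources used here, nor is whether Salmon estimates were rounded to whole numbers. Gene symbols were taken from the table, and 26530 of them matched a RefSeq gene table of the assembly UCB_Xtro_10.0, used for names and gene types. Totals per library run from 1329340 to 6351053 counts, and libraries of a group are distinct (chi-square per degree of freedom 5.18 to 14.7 between libraries of a group).

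The counts were analysed in R 4.3.3 with edgeR 4.0.16. After filtering with filterByExpr on the 5 groups, 8939 genes were tested, of which 1275 have a LOC, XB, xbg or MGC name. Libraries were scaled by TMM, and a model of 5 group means was fitted with robust quasi-likelihood dispersion estimates (biological coefficient of variation 0.286, 10 residual degrees of freedom). The 7 contrasts were EPO against control at 1.5 h and at 4.0 h, the mean of both, their difference, control culture at 1.5 h and at 4.0 h against fresh cells, and control culture at 4.0 h against 1.5 h. All tests are two-sided, p-values were adjusted by the Benjamini-Hochberg method within each contrast, and 0.05 was the threshold. Levels are TMM-scaled CPM as mean ± SD of 3 libraries. The SE of a log2 fold change is its size divided by the square root of the F statistic. For a gene with 3 or fewer counts in a group, the ratio of counts is given with a 95% counting interval. Groups of 3 against 3 independent libraries give no overlap for 10% of unchanged genes, a share that the pairing described below would change.

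The genes named were chosen by a rule. It takes, per comparison, the 10 largest rises and the 10 largest falls among genes with a readable symbol that passed the threshold, had no overlap between the groups' libraries and reached a mean of 10 CPM in the higher group (the overlap condition was dropped for the mean and the difference of the EPO effects). Where fewer than 5 genes passed, the 5 with the smallest p were taken. It adds up to 4 members per list past the threshold, and in every comparison epor, jak2, stat5a, stat5b, cish, socs1, socs2, socs3, pim1, bcl2l1, id1, tfrc, gata1, slc4a1, alas2, myc, fos and egr1. Lists were of EPO receptor pathway components, STAT5 and EPO target genes, immediate early genes, globins, erythroid membrane and transcription factors, heme synthesis, iron handling, thrombocytes, granulocytes and monocytes, T and NK cells, B cells, heat shock proteins, NF-kB and inflammatory response, interferon response, glycolysis and hypoxia, amino acid and ATF4 response, cell cycle, cholesterol synthesis, apoptosis and p53, ribosome biogenesis, proteasome, oxidative and NRF2 response, cytosolic ribosomal proteins and mitochondrially encoded genes. They were written from general knowledge, and which of the thrombocyte and leukocyte genes frog erythrocytes also express is not known here. Lists with at least 5 measured members (21) were tested with camera of limma 3.58.1 at its preset correlation of 0.01, adjusted over 147 list tests. Camera with an estimated correlation and fry were run as alternatives.

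Libraries with the same replicate number were checked for pairing on 1469 genes with a mean log2 CPM above 5, by the correlation of their deviations from the group means. The 30 pairs with the same number correlated at 0.270 to 0.622 (median 0.398), the 60 pairs with different numbers at -0.386 to 0.0459 (median -0.246), and each of the 15 libraries correlated best with libraries of its own number. The pairing comes from the data, since the labels give numbers only. The fit with the number as a block (coefficient of variation 0.241, 8 residual degrees of freedom) was an alternative, and its values are given beside results it changes.

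The comparisons, the lists, the rule for named genes and most alternatives were chosen before the data were examined. Those alternatives were DESeq2 size factors, no globin genes, the DESeq2 1.42.0 Wald test, limma voom, no filter on low counts, a mean of at least 10 CPM, only the groups compared, a 2-fold minimum change, the replicate block, and leaving out each library in turn. Added after the data were seen were thinning of every library to 1329340 counts, variants of the blocked fit, and leaving out 3 libraries that stood apart in depth or spread (fresh replicate 1, control at 4.0 h replicate 3 and EPO at 4.0 h replicate 2). Fresh replicate 3 was not among them, though it lay at -44.3 on both the first and the second principal component of log2 CPM. Leaving it out alone lowered the culture calls from 29 to 12 at 1.5 h and from 6 to 0 at 4.0 h. The scripts were tested on simulated data for EPO against control at 1.5 h, with 100 genes each changed 2-fold and 4-fold among 8463. Of these, 14% and 61% were recovered, with 0 false calls, and 32% and 72% with the block, with 5 false calls. A list of 25 genes shifted by 0.5 (log2) gave a camera p of 3.16e-08, and an unshifted list 0.488. The simulated genes were drawn independently given the replicate effects. The list check therefore does not show how the preset correlation performs on correlated genes. Shared comparison groups were handled by simulating unchanged groups in 10 draws. Reads, splicing and strand were not analysed here. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.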

Results

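Gene expression was measured by 3' RNA-seq in total peripheral blood cells of wild-type Xenopus tropicalis, taken from the heart. The 15 libraries fall into 5 groups of 3: fresh cells before culture, and cells kept in culture medium for 1.5 h or 4.0 h with or without 1 ng/mL erythropoietin (EPO). EPO is the hormone that drives red cell production through its receptor, Janus kinase 2 and STAT5, and the preparation used here was recombinant X. tropicalis EPO made in E. coli. Frog erythrocytes keep their nucleus and circulate with nucleated thrombocytes and leukocytes, so each library reads a mixture of cells.

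The fresh libraries held 1329340, 2329659 and 1817170 counts (replicates 1, 2 and 3). The control libraries held 2350234, 4472724 and 2550448 counts at 1.5 h, and 2972137, 3388564 and 1958663 at 4.0 h. The EPO libraries held 3904765, 5868379 and 5847832 counts at 1.5 h, and 5712197, 2287764 and 6351053 at 4.0 h. The EPO groups were therefore sequenced more deeply on average (5206992 ± 1127808 and 4783671 ± 2184994 counts, SD, n = 3) than the control groups (3124469 ± 1171907 and 2773121 ± 735432) and the fresh group (1825390 ± 500210). At these depths 3 counts correspond to between 0.472 and 2.26 CPM (counts scaled to a common library total) in a single library. Intervals and floors given here cover counting error only, because PCR reads without molecular identifiers are not independent molecules.

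The 12 globin genes in the table took between 41.9% and 48.4% of the counts, with hba1 at 22.3% and hbg1 at 16.4% of all counts. The ferritin gene fth1.1 took 2.54%, the cytosolic ribosomal protein genes between 18.0% and 21.2% per library, and alas2, the first enzyme of heme synthesis in red cells, lay at 3925 ± 437 CPM in fresh cells (SD, n = 3). Genes listed for other blood cells were present at lower levels in fresh cells. The tubulin gene tubb1 of the thrombocyte list lay at 354 ± 48.4 CPM. Of the granulocyte and monocyte list, mmp9.1 and alox5ap lay at 162 ± 47.9 and 139 ± 17.5 CPM (SD, n = 3). Whether frog erythrocytes also express these genes is not known here, so their levels do not measure the share of other cells. Of the T and NK cell and B cell genes in the table, 4 of 22 and 2 of 16 had enough counts to be tested, and neither list was tested. No mitochondrially encoded gene was in the table. The DNA polymerase epsilon subunit gene pole2 ranked 18 by counts with 0.410% of them and lay at 4186 ± 48.6 CPM in fresh cells (SD, n = 3). Whether the reads counted for pole2 come from that gene was not tested. Globin genes, atf5.2, itga2b.1 and itga2b.2, mmp9.1 and mmp9.2, and hspa1b may have similar copies with which reads are shared. How alike the copies are was not tested, so their values are uncertain.

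**Figure D1:**
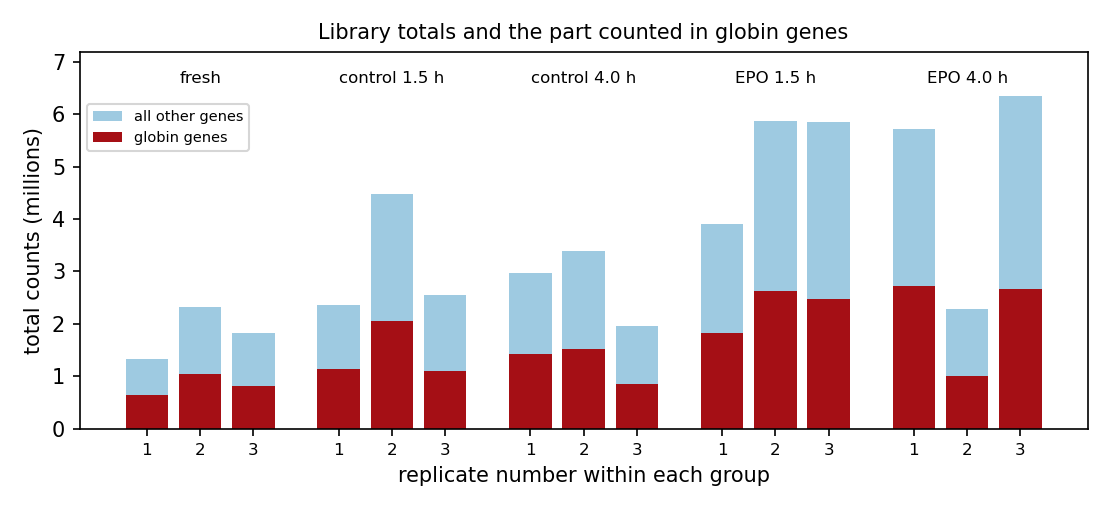
Total counts (y axis) of each of the 15 libraries by group and replicate number, with the part counted in globin genes in red. Totals run from 1329340 (fresh replicate 1) to 6351053 (EPO at 4.0 h, replicate 3), and globin genes take between 41.9% and 48.4% of each.

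The first comparison asked which genes respond to EPO within 1.5 h. The clearest responder of the EPO receptor's own pathway was cish, which encodes an inhibitor of cytokine receptor signalling and is a STAT5 target. It rose from 96.0 ± 8.02 CPM in control to 366 ± 1.06 CPM with EPO (SD, n = 3), a log2 fold change of 1.93 ± 0.350 (SE, adjusted p = 0.0337). A set of genes of the amino acid response rose with it. Among them were ddit3, which encodes the stress transcription factor CHOP (log2 fold change 1.58 ± 0.251, adjusted p = 4.43e-04), and the transcription factor gene atf5.2 (1.38 ± 0.204, adjusted p = 1.82e-04). They included the amino acid transporter genes slc3a2 (1.50 ± 0.314, adjusted p = 0.0218) and slc1a5 (1.66 ± 0.364, adjusted p = 0.0291), and the asparaginyl-tRNA synthetase gene nars1 (1.70 ± 0.347, adjusted p = 0.0115). The largest falls were in azin2, an antizyme inhibitor gene (-2.69 ± 0.546, adjusted p = 0.0132), and in the sestrin gene sesn1 (-2.52 ± 0.388, adjusted p = 5.79e-04), which went from 31.1 ± 13.8 to 5.35 ± 2.21 CPM (SD, n = 3).

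The other large rises at 1.5 h were those of the RING finger gene rnf227 (2.19 ± 0.335, adjusted p = 2.46e-04), coq10b (2.10 ± 0.419, adjusted p = 0.0498) and the actin-binding protein gene lima1 (1.86 ± 0.253, adjusted p = 4.53e-05). Next came the Hsp70-binding protein gene hspbp1 (1.82 ± 0.418, adjusted p = 0.0339), the kinase gene mapk6 (1.78 ± 0.293, adjusted p = 5.79e-04) and the repressor gene etv6 (1.70 ± 0.363, adjusted p = 0.0186). The small Maf gene maff (1.29 ± 0.170, adjusted p = 3.34e-05), klf10 (1.48 ± 0.358, adjusted p = 0.0493) and the Hsp40 gene dnaja1 (1.09 ± 0.247, adjusted p = 0.0325) also rose. So did irf7 (1.03 ± 0.247, adjusted p = 0.0457) and the glutathione synthesis gene gclc (1.27 ± 0.254, adjusted p = 0.00936). The apelin receptor gene aplnr (-1.07 ± 0.244, adjusted p = 0.0325) and the acetylcholine receptor subunit gene chrna4 (-0.95 ± 0.224, adjusted p = 0.0394) fell. For each of these genes the 3 EPO libraries lay wholly above or wholly below the 3 control libraries. The rule required this of the largest rises and falls, so it is no added evidence for them.

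Among 8939 genes tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 34 rose and 5 fell. With the replicate number as a block these counts were 96 and 43. At an unadjusted p of 0.05, 637 genes passed, against 447 for independent libraries, and the groups did not overlap for 1320 genes (14.8%, against 10% for independent libraries). Libraries of the same replicate number deviate together, so 447 and 10% are not the values that unchanged groups of these samples would give, here and in the comparisons that follow. The count of 39 calls became 18 without control replicate 2, 19 without control replicate 3, 13 without EPO replicate 1 and 16 without EPO replicate 3. Of the 21 calls named, atf5.2, ddit3, lima1, maff, mapk6, rnf227 and sesn1 (7) kept their adjusted p below 0.05 without any 1 library, and cish, coq10b, hspbp1 and klf10 (4) lost it without each of the 6 in turn. Without control replicates 1, 2 and 3 in turn, 7, 12 and 12 of the 21 were lost, and without EPO replicates 1, 2 and 3 in turn 14, 6 and 13. For cish the log2 fold change without 1 library lay between 1.87 and 2.00, with an adjusted p between 0.101 and 0.177. With the block its adjusted p was 6.54e-05, and at most 7.06e-04 in 7 variants of the blocked fit.

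**Figure D2:**
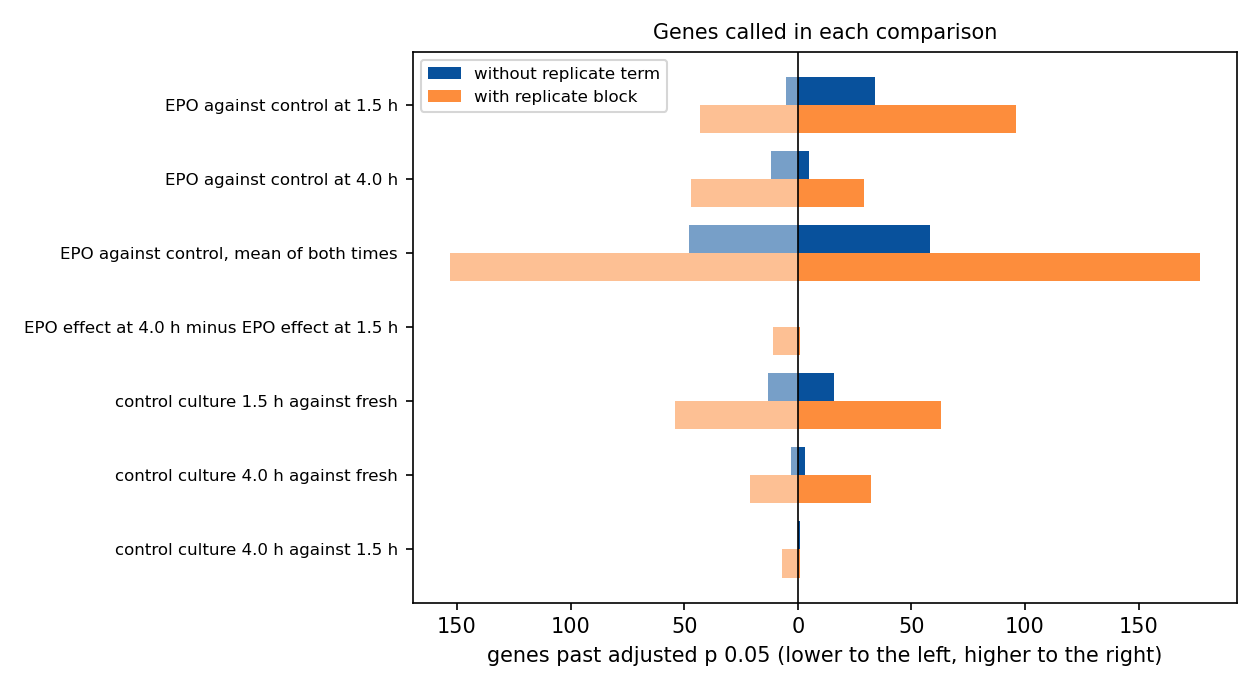
Number of genes past an adjusted p of 0.05 (x axis, lower to the left, higher to the right) in each of the 7 comparisons, without (blue) and with (orange) the replicate number as a block. The mean EPO effect calls the most genes, 58 higher and 48 lower without the block and 177 and 153 with it.

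A further 3 genes of the receptor's pathway passed with the block and in some other alternatives (epor in 6 of 16, socs1 in 4 and myc in 6, the block included). The EPO receptor gene epor lay at 161 ± 17.9 CPM in control and 76.2 ± 36.6 CPM with EPO (SD, n = 3), a log2 fold change of -1.08 ± 0.288 (adjusted p = 0.196). With the block its adjusted p was 0.0435, and it ranged from 1.62e-05 to 0.562 over its 16 alternatives. In 7 variants of the blocked fit epor passed in 4 (adjusted p up to 0.548), socs1 in 6 (up to 0.0975) and myc in 5 (up to 0.0863). Without EPO replicate 2 epor passed without the block as well (-1.52, adjusted p = 6.45e-04). The feedback inhibitor gene socs1 lay at 43.7 ± 17.1 and 117 ± 9.67 CPM (1.44 ± 0.538, adjusted p = 0.537), with an adjusted p of 7.11e-04 with the block and from 3.69e-04 to 0.934 over 16 alternatives. The transcription factor gene myc had a log2 fold change of 1.08 ± 0.268 (adjusted p = 0.0575), with an adjusted p of 0.00220 with the block and from 0.00220 to 0.376 over 16 alternatives. The remaining genes followed in every comparison did not pass in either fit. Their log2 fold changes were 1.46 ± 0.615 for socs2, 0.89 ± 0.460 for socs3, 0.90 ± 0.612 for egr1, 0.51 ± 0.268 for pim1, 0.34 ± 0.433 for fos, 0.26 ± 0.245 for jak2 and 0.27 ± 0.227 for gata1 (adjusted p between 0.560 and 0.965). The erythroid genes slc4a1 (-0.29 ± 0.163), alas2 (-0.05 ± 0.123) and tfrc (-0.12 ± 0.543) and the survival gene bcl2l1 (-0.04 ± 0.163) lay close to 0. The table holds no stat5a or id1, and stat5b had 27 counts in all and was not tested.

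Among gene lists, the 26 measured genes of the amino acid and ATF4 response had a median log2 fold change of 0.52 at 1.5 h, with 21 higher and 6 called as risen (camera adjusted p = 3.18e-08). Adjusted over the list alone, 11 rose. The 30 heat shock protein genes had a median of 0.60, with 28 higher, 1 called and 6 called adjusted over the list alone (camera adjusted p = 5.76e-08). That list had an adjusted p = 0.405 with an estimated correlation. The 20 STAT5 and EPO target genes had a median of 0.59, with 15 higher and 1 (cish) called, and 3 risen and 1 fallen adjusted over the list alone (camera adjusted p = 0.00588, adjusted p = 0.402 with an estimated correlation). Of the 78 cytosolic ribosomal protein genes 76 were lower, by a median of -0.10, with 0 called by edgeR in all genes or adjusted over the list alone (camera adjusted p = 0.00787, adjusted p = 0.951 with an estimated correlation). With the replicate block 8 ATF4 response, 7 heat shock and 4 STAT5 target genes rose. Over all 7 comparisons 15 of 147 list results passed camera with its preset correlation, and those of the ATF4 response at 1.5 h and in the mean of both times are the 2 that hold with an estimated correlation.

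The second comparison asked which genes differ with EPO at 4.0 h. Genes of the ATF4 response rose again. The amino acid transporter gene slc3a2 went from 18.1 ± 5.37 to 54.8 ± 23.5 CPM (SD, n = 3, log2 fold change 1.60 ± 0.316, adjusted p = 0.0302). The other rises were those of ddit3 (1.18 ± 0.251, adjusted p = 0.0316), atf5.2 (1.1 ± 0.207, adjusted p = 0.0134), bcl2l14 of the BCL2 family (0.91 ± 0.191, adjusted p = 0.0302) and the syntenin gene sdcbp (0.81 ± 0.176, adjusted p = 0.0336). These 5 genes had also risen at 1.5 h. The largest fall was in the homeobox gene six3 (-2.41 ± 0.477, adjusted p = 0.0206). It lay at 12 ± 1.66 CPM in control and 2.27 ± 0.525 CPM with EPO, beside 8.96 ± 1.35 CPM in fresh cells and 4.59 ± 0.537 CPM in control at 1.5 h (SD, n = 3). Also lower were tmem25 (-1.60 ± 0.330, adjusted p = 0.0302), the kinase gene stk39 (-1.19 ± 0.257, adjusted p = 0.0336), chrna4 (-1.04 ± 0.226, adjusted p = 0.0336) and the potassium channel gene kcnk2 (-0.98 ± 0.180, adjusted p = 0.0134). Other falls under 2-fold were those of gng4, sgcb, cavin4 and aig1, with log2 fold changes of -0.98 ± 0.218, -0.92 ± 0.191, -0.86 ± 0.190 and -0.84 ± 0.177 (adjusted p between 0.0302 and 0.0414).

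The genes of the receptor's pathway did not pass at 4.0 h in either fit. The log2 fold change of cish was -0.65 ± 0.40 (16 ± 2.40 CPM with EPO and 25.8 ± 11.8 CPM in control, SD, n = 3, adjusted p = 0.825). Over 16 alternatives it ranged from -0.91 to -0.26, the latter without control replicate 3, and 0 passed. The log2 fold change was -1.0 ± 0.545 for socs3, -0.45 ± 0.286 for epor, -0.33 ± 0.627 for socs2, -0.28 ± 0.309 for myc, 0.07 ± 0.672 for socs1 and 0.36 ± 0.227 for gata1. Those of jak2 (0.07), pim1 (-0.03), bcl2l1 (0.09), tfrc (-0.12), slc4a1 (0.09), alas2 (-0.07), fos (-0.54) and egr1 (0.14) did not pass either (edgeR adjusted p between 0.799 and 0.999 for these 15 genes).

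By edgeR's quasi-likelihood test 5 genes rose and 12 fell at 4.0 h, and 29 and 47 with the replicate block. At an unadjusted p of 0.05, 635 genes passed, against 447 for independent libraries, and the groups did not overlap for 1285 genes (14.4%, against 10% for independent libraries). The 17 calls became 9, 4, 7 and 0 without control replicate 2, control replicate 3, EPO replicate 2 and EPO replicate 3. Their balance was not stable. Rises and falls were 2 and 2 without control replicate 3, and 4 and 3 without EPO replicate 2. They were 3 and 1 without the 3 libraries that stood apart. More falls remained without control replicates 1 and 2 and EPO replicate 1 (3 and 9, 1 and 8, 1 and 11). None of the 14 named calls kept an adjusted p below 0.05 without each library in turn. Without control replicates 1, 2 and 3 in turn 7, 9 and 14 were lost, and without EPO replicates 1, 2 and 3 in turn 8, 10 and 14. The ATF4 response list had a median of 0.41, with 21 of 26 genes higher, 3 called and 7 called adjusted over the list alone (camera adjusted p = 1.34e-04, adjusted p = 0.183 with an estimated correlation). The heat shock list had a median of 0.42, with 25 of 30 higher, 0 called by edgeR in all genes or adjusted over the list alone, and 3 with the block (camera adjusted p = 3.12e-05, adjusted p = 0.787 with an estimated correlation).

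The third comparison took the mean EPO effect over both times, which uses 6 EPO and 6 control libraries. These carry only 3 replicate numbers, and libraries of a number deviate together. Neither fit allows the EPO effect to differ between numbers. If both times of a number are not independent, the p-values here may be too small. The genes that rose most were slc3a2 (1.55 ± 0.223, adjusted p = 1.47e-04) and nars1 (1.47 ± 0.248, adjusted p = 4.34e-04). They were followed by klf10 (1.46 ± 0.256, adjusted p = 8.28e-04), rnf227 (1.44 ± 0.235, adjusted p = 2.79e-04), the tetraspanin gene cd37 (1.40 ± 0.339, adjusted p = 0.0264) and ddit3 (1.38 ± 0.177, adjusted p = 1.38e-05). The strongest evidence was for atf5.2 (1.24 ± 0.145, adjusted p = 4.58e-06). The genes that fell most were azin2 (-2.56 ± 0.386, adjusted p = 1.62e-04), sesn1 (-2.02 ± 0.267, adjusted p = 5.11e-05), the cell cycle inhibitor gene cdknx (-1.82 ± 0.312, adjusted p = 0.0152) and the homeobox gene hoxc4 (-1.60 ± 0.317, adjusted p = 0.00385). Beyond these, hspbp1, gtf2h1, ralgds and etv6 rose by 1.26 to 1.35 (adjusted p between 2.54e-04 and 0.0115). Falls of -0.95 to -1.40 were found for ddx6, tyw5, tmem25, ssh2, chrna4 and il17rd (adjusted p between 2.15e-04 and 0.0335).

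Smaller rises in the mean of both times came from the immediate early, stress and interferon lists. They were those of maff (0.81 ± 0.120, adjusted p = 7.71e-05), gclc (1.04 ± 0.182, adjusted p = 8.28e-04), dnaja1 (0.72 ± 0.172, adjusted p = 0.0256) and the cytosolic Hsp90 gene hsp90ab1 (0.55 ± 0.137, adjusted p = 0.0335). Of the interferon list they were irf7 (0.90 ± 0.174, adjusted p = 0.00282), irf9 (0.64 ± 0.143, adjusted p = 0.0130) and the peptide transporter gene tap1 (0.81 ± 0.208, adjusted p = 0.0409). The genes epor (-0.76 ± 0.203, adjusted p = 0.0883), socs1 (0.76 ± 0.429, adjusted p = 0.554) and the erythroid transcription factor gene gata1 (0.32 ± 0.160, adjusted p = 0.446) passed with the replicate block, at adjusted p of 0.0203, 0.0436 and 0.0166. Over 22 alternatives each, the block included, their adjusted p ranged from 1.43e-05 to 0.223, from 0.0436 to 0.844 and from 0.0166 to 0.695, and 7, 1 and 1 passed. In 7 variants of the blocked fit they passed in 6, 5 and 4, with adjusted p up to 0.299, 0.266 and 0.556. The log2 fold changes of cish (0.64 ± 0.263), myc (0.40 ± 0.204), socs2 (0.57 ± 0.438), egr1 (0.52 ± 0.478) and pim1 (0.24 ± 0.198) did not pass. Nor did those of jak2 (0.16 ± 0.174), socs3 (-0.05 ± 0.349), fos (-0.10 ± 0.322), bcl2l1 (0.02 ± 0.115), tfrc (-0.12 ± 0.381), slc4a1 (-0.10 ± 0.115) and alas2 (-0.06 ± 0.0868).

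In the mean of both times 58 genes rose and 48 fell by edgeR's quasi-likelihood test, and 177 rose and 153 fell with the replicate block. At an unadjusted p of 0.05, 1056 genes passed, against 447 for independent libraries. The 106 calls became 66 without the 1.5 h EPO replicate 1 and 67 without the 1.5 h EPO replicate 3. Their balance was not stable. The 58 rises became 34 and 36 without EPO replicate 1 of 1.5 h and of 4.0 h. The 48 falls became 23 without the 4.0 h control replicate 3, 26 without the 4.0 h EPO replicate 2, 27 without the 1.5 h EPO replicate 3 and 30 without the 1.5 h control replicate 3. Without the 3 libraries that stood apart (fresh replicate 1, and the 4.0 h control replicate 3 and EPO replicate 2) there were 60 rises and 19 falls. Of the 28 named calls 18 kept an adjusted p below 0.05 without any 1 of the 12 libraries, and between 2 and 7 were lost without each of them. The 7 were lost without the 1.5 h EPO replicate 1.

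The ATF4 response list stood out in the mean of both times too, with a median of 0.52, 22 of 26 genes higher, 6 called and 12 called adjusted over the list alone (camera adjusted p = 3.18e-08). The heat shock list had a median of 0.53, with 27 of 30 higher, 2 called and 14 called adjusted over the list alone (camera adjusted p = 1.35e-08, adjusted p = 0.402 with an estimated correlation). With the replicate block 9 ATF4 response and 10 heat shock genes rose, and the heat shock list also passed with an estimated correlation (adjusted p = 0.0261). The STAT5 and EPO target list (median 0.42, 15 of 20 higher, 0 called, camera adjusted p = 0.0855) and the cytosolic ribosomal protein list (median -0.06, 75 of 78 lower, 0 called, camera adjusted p = 0.0912) passed only with the block. There they had adjusted p of 0.0300 and 0.0240, and adjusted p = 0.302 and 0.914 with an estimated correlation.

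**Figure D3:**
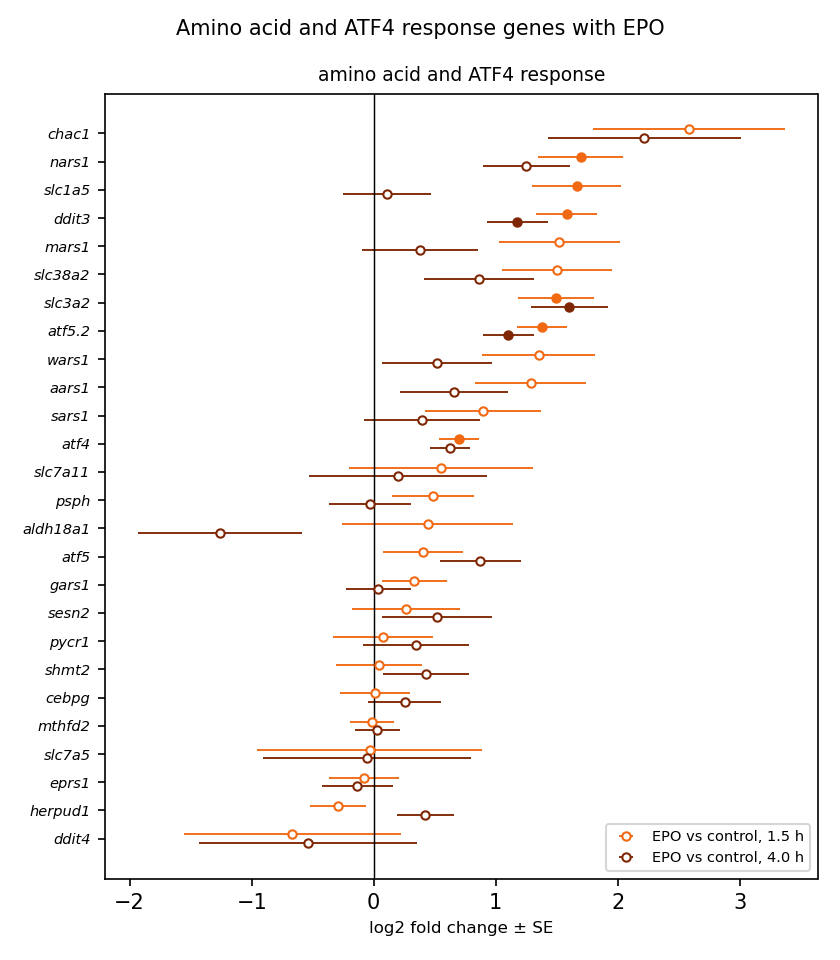
Log2 fold change with EPO against control (x axis, ± SE) of the 26 measured genes of the amino acid and ATF4 response, at 1.5 h (light) and 4.0 h (dark), 3 libraries per group, with filled points past an adjusted p of 0.05. At each time 21 of the 26 genes lie above 0, with ddit3, atf5.2 and slc3a2 filled at both.

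The lists that hold the erythroid program did not pass in the mean of both times. Medians and camera adjusted p were -0.10 and 0.369 for 10 globin genes and 0.00 and 0.984 for 25 erythroid membrane and transcription factor genes. They were 0.08 and 0.535 for 21 heme synthesis genes, 0.12 and 0.310 for 11 iron handling genes and 0.11 and 0.959 for 19 EPO receptor pathway components. Adjusted over the list alone, 2 of the receptor pathway components fell, 1 erythroid gene rose and 1 fell, 1 heme synthesis gene rose, and 0 globin or iron handling genes were called by edgeR. Markers of other blood cells did not pass either, with -0.02 and 0.991 for 13 thrombocyte genes (0 called adjusted over the list alone) and 0.05 and 0.826 for 20 granulocyte and monocyte genes (1 risen and 1 fallen adjusted over the list alone).

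Of the remaining lists, 3 interferon response genes rose (22 measured, median 0.11, camera adjusted p = 0.166, 3 adjusted over the list alone). In the immediate early list 2 genes rose (26 measured, median -0.03, camera adjusted p = 0.709, 2 risen and 3 fallen adjusted over the list alone), and in the oxidative and NRF2 response list 1 (25 measured, median 0.12, camera adjusted p = 0.321, 2 risen adjusted over the list alone). In the apoptosis and p53 list sesn1 fell (24 measured, median 0.05, camera adjusted p = 0.874, 1 risen and 1 fallen adjusted over the list alone). No gene was called by edgeR in all genes tested among 20 NF-kB and inflammatory response genes (median 0.18, camera adjusted p = 0.339), 23 glycolysis and hypoxia genes (0.07, 0.241) and 10 cell cycle genes (-0.12, 0.783). The same holds for 21 cholesterol synthesis genes (0.11, 0.454), 46 ribosome biogenesis genes (0.06, 0.142) and 31 proteasome genes (0.08, 0.337). Adjusted over the list alone 3 glycolysis and 1 ribosome biogenesis genes rose and 0 of the other lists' genes were called. Median, mean and camera direction differed in sign for the receptor pathway, immediate early, erythroid, thrombocyte, cell cycle and apoptosis lists. In the other comparisons they differed for 25 of 126 list results, the lowest camera adjusted p of which was 0.593.

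The fourth comparison asked whether the EPO effect differs between 4.0 h and 1.5 h. Without the block no gene passed by edgeR's quasi-likelihood test (0 of 8939), with 228 at an unadjusted p of 0.05 (447 for independent libraries), 0 by DESeq2 and 2 by voom. With the replicate block 1 gene had a higher and 11 a lower signed log2 fold change with EPO at 4.0 h than at 1.5 h. The gene cish carried the widest gap of those named, with a difference in log2 fold change of -2.59 ± 0.529 (adjusted p = 0.813) and -2.60 ± 0.369 with the block (adjusted p = 0.00490). Over its 22 alternatives, the block included, the adjusted p of cish ranged from 1.02e-10 to 1.00 and 5 passed. The differences of ldlrad4 (-1.53 ± 0.337, adjusted p = 0.371), lima1 (-1.59 ± 0.356, adjusted p = 0.371) and maff (-0.95 ± 0.239, adjusted p = 0.813) passed with the block too, at adjusted p of 0.00772, 0.0127 and 0.0265. Of 22 alternatives 2, 2 and 1 passed, the block included, and the further one for ldlrad4 and lima1 was the fit without a filter on low counts. Each of the 3 had an adjusted p of 1.00 in at least 1 of 22 alternatives and none below its value with the block, and in 7 variants of the blocked fit they passed in 5, 3 and 3. For mapk6 the difference was -1.66 ± 0.440 (adjusted p = 0.962), for myc -1.36 ± 0.409, for socs3 -1.89 ± 0.713, for socs2 -1.80 ± 0.879, for socs1 -1.37 ± 0.864 and for epor 0.63 ± 0.404, and these did not pass in either fit. The differences of jak2, pim1, bcl2l1, tfrc, gata1, slc4a1, alas2, fos and egr1 lay between -0.88 and 0.38 and did not pass in either fit. The STAT5 and EPO target list had a median difference of -0.35, with 15 of 20 genes lower, 0 called by edgeR and 2 fallen adjusted over the list alone (camera adjusted p = 0.10). With the block it passed (adjusted p = 0.0244, and adjusted p = 0.302 with an estimated correlation). The medians of the ATF4 response and heat shock lists differed by -0.29 and -0.15 between the times (camera adjusted p = 0.556 and 0.947).

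**Figure D4:**
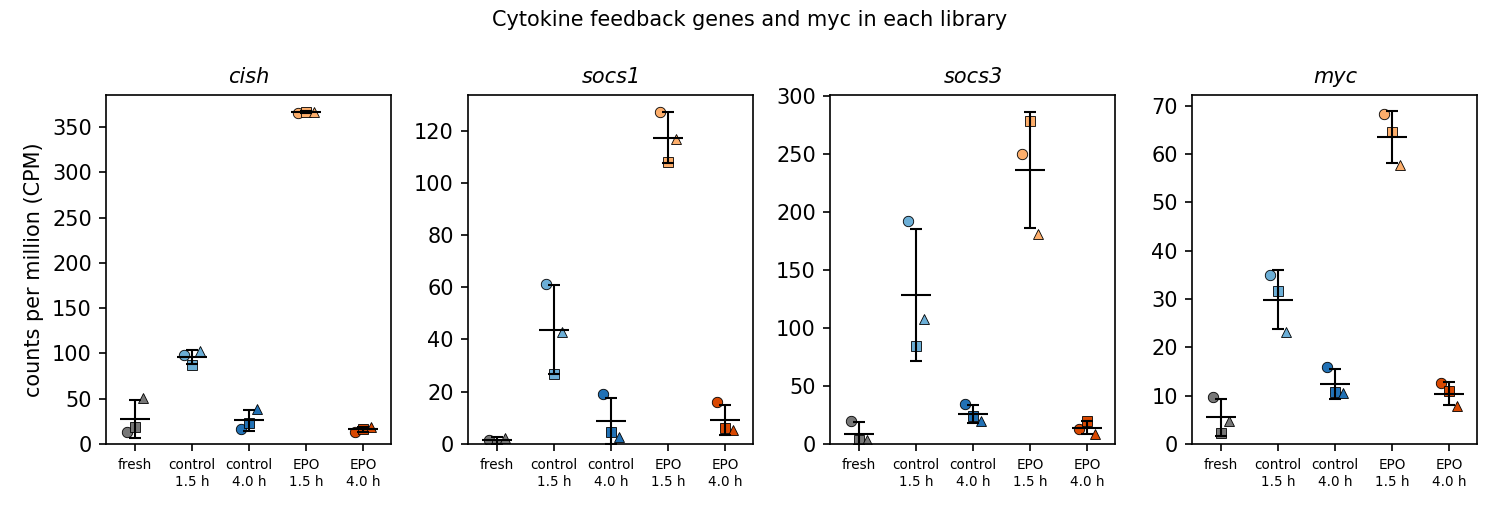
CPM (y axis, linear) of cish, socs1, socs3 and myc in each library of the 5 groups, with symbols for replicate numbers and bars for the mean ± SD of 3 libraries. With EPO at 1.5 h cish reaches 366 ± 1.06 CPM, against 16 ± 2.40 CPM with EPO at 4.0 h.

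The fifth comparison asked what culture without EPO changed within 1.5 h, which is the background against which EPO acts. The transcription factor genes fos (4.55 ± 0.723, adjusted p = 0.00534), myc (2.57 ± 0.360, adjusted p = 1.34e-04) and irf1 (2.87 ± 0.497, adjusted p = 0.0469) rose. The feedback inhibitor gene socs3 went from 8.83 ± 9.62 to 128 ± 56.9 CPM (SD, n = 3, 4.01 ± 0.621, adjusted p = 0.0247). The vasodilator hormone gene adm had 1 count in the fresh libraries and 148 after 1.5 h of culture (adjusted p = 6.93e-05), a ratio of 90.2 with a 95% counting interval of 15.9 to 3587. Its adjusted p was 0.0864 with voom, and its fitted log2 fold change went from 6.34 to 9.04 without fresh replicate 3. The polyamine synthesis gene odc1 (2.67 ± 0.521, adjusted p = 0.0232), strada (2.35 ± 0.530, adjusted p = 0.0361) and gadd45g (2.16 ± 0.316, adjusted p = 0.00912) rose as well. So did rasl11b (1.56 ± 0.276, adjusted p = 0.0119), sbno2 (1.44 ± 0.266, adjusted p = 0.00540) and the NF-kB inhibitor gene nfkbia (1.26 ± 0.251, adjusted p = 0.0232). The phosphatase gene dusp1 fell from 40.9 ± 25.3 to 9.84 ± 1.69 CPM (SD, n = 3, -2.04 ± 0.396, adjusted p = 0.00912). Falls near 2-fold were those of nab2 (-1.28 ± 0.277), bin3 (-1.18 ± 0.260), noxred1 (-1.13 ± 0.199), kcnk2 (-1.0 ± 0.180) and lcp2 (-0.92 ± 0.21), with adjusted p between 0.00511 and 0.0406.

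In that comparison cish lay at 27.4 ± 20.6 CPM in fresh cells and 96.0 ± 8.02 CPM after 1.5 h (SD, n = 3, 1.80 ± 0.389, adjusted p = 0.0926). It passed with the replicate block (adjusted p = 0.00132), and its adjusted p ranged from 7.33e-11 to 0.225 over 16 alternatives. The gene socs1 lay at 1.27 ± 1.18 CPM in fresh cells, where 1 library had no count, and at 43.7 ± 17.1 CPM after 1.5 h (adjusted p = 0.0623). With the block it passed at an adjusted p of 3.05e-07, the lowest over 16 alternatives, of which the highest was 0.186. Both genes passed in 7 of 7 variants of the blocked fit. The log2 fold changes of pim1 (1.04 ± 0.30), egr1 (0.66 ± 0.705), tfrc (0.36 ± 0.607), bcl2l1 (0.27 ± 0.168), epor (0.10 ± 0.289), slc4a1 (0.10 ± 0.164), jak2 (0.08 ± 0.255), alas2 (0.03 ± 0.123), gata1 (-0.03 ± 0.232) and socs2 (-0.85 ± 0.668) did not pass in either fit.

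By edgeR's quasi-likelihood test 16 genes rose and 13 fell after 1.5 h of culture, and 63 and 54 with the replicate block. At an unadjusted p of 0.05, 866 genes passed, against 447 for independent libraries, and the groups did not overlap for 1214 genes (13.6%, against 10% for independent libraries). The 29 calls became 19 without fresh replicate 1, 12 without fresh replicate 3, and 11, 7 and 19 without control replicates 1, 2 and 3. Of the 17 named calls, adm, myc, noxred1 and sbno2 (4) kept an adjusted p below 0.05 without any 1 library, and irf1 and lcp2 (2) lost it without each of the 6 in turn. Without fresh replicates 1, 2 and 3 in turn 7, 6 and 11 of the 17 were lost, and without control replicates 1, 2 and 3 in turn 10, 11 and 8.

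The immediate early list lay higher after 1.5 h of culture, with a median of 0.71, 20 of 26 genes higher, 3 risen and 1 fallen, and 9 risen and 2 fallen adjusted over the list alone (camera adjusted p = 3.94e-05, adjusted p = 0.402 with an estimated correlation). The STAT5 and EPO target list had a median of 0.32, with 16 of 20 higher, 2 risen, and 6 risen and 1 fallen adjusted over the list alone (camera adjusted p = 0.00588, adjusted p = 0.402 with an estimated correlation). The immediate early list shares dusp5, egr1 and myc with the STAT5 target list. Markers of other blood cells lay lower. Of 13 thrombocyte genes 9 were lower, by a median of -0.53, with 0 called by edgeR, 1 fallen adjusted over the list alone and 1 fallen with the block (camera adjusted p = 0.00638, adjusted p = 0.839 with an estimated correlation). Of 20 granulocyte and monocyte genes 18 were lower, by a median of -0.55, with 0 called by edgeR, 1 fallen adjusted over the list alone and 1 fallen with the block (camera adjusted p = 0.00487, adjusted p = 0.839 with an estimated correlation). The heat shock list (median 0.29, 21 of 30 higher, 0 called by edgeR, 1 risen adjusted over the list alone, camera adjusted p = 0.156) passed with the block at an adjusted p of 0.0458 (adjusted p = 0.302 with an estimated correlation).

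**Figure D5:**
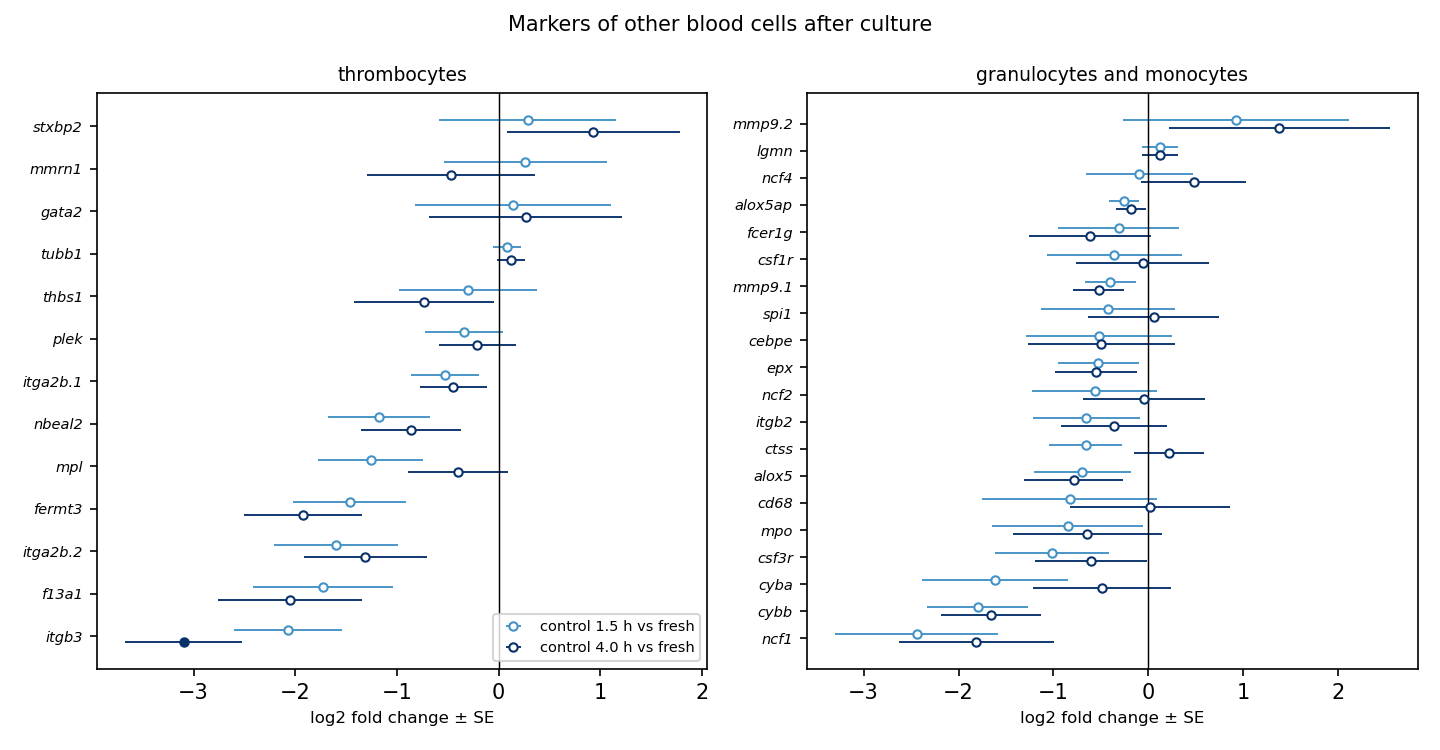
Log2 fold change in control culture against fresh cells (x axis, ± SE) of 13 thrombocyte and 20 granulocyte and monocyte genes, at 1.5 h (light) and 4.0 h (dark), 3 libraries per group, with filled points past an adjusted p of 0.05. At 1.5 h 9 of the thrombocyte and 18 of the granulocyte and monocyte genes lie below 0, with itgb3 at 4.0 h the filled point at -3.10 ± 0.576.

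The sixth comparison asked the same after 4.0 h of culture. The integrin gene itgb3 of thrombocytes fell from 21.0 ± 8.72 to 2.41 ± 0.845 CPM (SD, n = 3, -3.10 ± 0.576, adjusted p = 0.0244), and dusp1 was again lower than in fresh cells (-2.06 ± 0.399, adjusted p = 0.0259). The genes rnf227 (2.48 ± 0.484, adjusted p = 0.0259) and ppp1r15b, a regulator of translation initiation (1.16 ± 0.243, adjusted p = 0.0468), rose. For adm there were 50 counts against 1 in fresh cells (adjusted p = 0.0259), a ratio of 32.7 with a 95% counting interval of 5.61 to 1319. The gene fos (3.59 ± 0.767, adjusted p = 0.162) passed with the replicate block (adjusted p = 4.98e-05, from 1.60e-08 to 0.840 over 16 alternatives). So did socs1 (2.96 ± 1.15, adjusted p = 0.527), at an adjusted p of 0.0468 with the block, the lowest over 15 alternatives, of which the highest was 0.871. In 7 variants of the blocked fit fos passed in 7 and socs1 in 2 (adjusted p up to 0.419). The log2 fold changes of myc (1.31 ± 0.386), socs3 (1.74 ± 0.659), tfrc (0.60 ± 0.60), cish (-0.13 ± 0.412), egr1 (-0.85 ± 0.775) and socs2 (-0.35 ± 0.655) did not pass in either fit, nor did those of epor, jak2, pim1, bcl2l1, gata1, slc4a1 and alas2, which lay between -0.03 and 0.28.

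By edgeR's quasi-likelihood test 3 genes rose and 3 fell after 4.0 h of culture, and 32 and 21 with the replicate block. The sixth call, LOC100492529, was lower and was named after its values were seen. At an unadjusted p of 0.05, 724 genes passed, against 447 for independent libraries, and the groups did not overlap for 1039 genes (11.6%, against 10% for independent libraries). The 6 calls became 11 without fresh replicate 2, 0 without fresh replicate 3 and 1 without control replicate 1. Of the 5 named calls none kept an adjusted p below 0.05 without each library in turn, and 4, 1 and 5 were lost without fresh replicates 1, 2 and 3 and 5, 3 and 2 without control replicates 1, 2 and 3. The fitted log2 fold change of adm rose to 7.48 without fresh replicate 3. The immediate early list had a median of 0.51, with 20 of 26 higher, 1 fallen, and 7 risen and 2 fallen adjusted over the list alone (camera adjusted p = 0.00638, adjusted p = 0.716 with an estimated correlation). The granulocyte and monocyte list had a median of -0.43, with 14 of 20 lower and 0 called by edgeR in all genes or adjusted over the list alone (camera adjusted p = 0.241). The thrombocyte list had a median of -0.46, with 10 of 13 lower, 1 fallen and 3 fallen adjusted over the list alone (camera adjusted p = 0.00787, adjusted p = 0.839 with an estimated correlation). The heat shock list (median 0.22, 0 called by edgeR, 5 risen adjusted over the list alone, camera adjusted p = 0.109) passed with the block at an adjusted p of 0.0303 (adjusted p = 0.302 with an estimated correlation).

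The seventh comparison set control culture at 4.0 h against 1.5 h. The gene cish went from 96.0 ± 8.02 to 25.8 ± 11.8 CPM (SD, n = 3, -1.93 ± 0.38, adjusted p = 0.529). The gene socs1 went from 43.7 ± 17.1 to 8.69 ± 8.94 CPM (-2.25 ± 0.634, adjusted p = 0.999) and gadd45g from 364 ± 17 to 120 ± 10.8 CPM (-1.60 ± 0.305, adjusted p = 0.487). With myc (-1.26 ± 0.297, adjusted p = 0.487) and rasl11b (-1.15 ± 0.266, adjusted p = 0.535), these passed with the block, at adjusted p of 0.00233, 3.40e-04, 0.0114, 0.0132 and 1.40e-06. Of 16 alternatives each, the block included, 7, 2, 6, 2 and 5 passed, and the adjusted p of these 5 genes ranged up to 1.00 and down to 6.54e-12, 3.40e-04, 1.69e-13, 0.0132 and 1.40e-06. In 7 variants of the blocked fit they passed in 7, 7, 6, 4 and 7. The log2 fold changes of deaf1 (-2.62 ± 0.663), socs3 (-2.28 ± 0.508), egr1 (-1.51 ± 0.709), pim1 (-1.07 ± 0.288), fos (-0.96 ± 0.466) and socs2 (0.49 ± 0.658) did not pass in either fit, nor did those of epor, jak2, bcl2l1, tfrc, gata1, slc4a1 and alas2, which lay between -0.18 and 0.24.

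By edgeR's quasi-likelihood test 1 gene (LOC116408795, named after its values were seen) rose and 0 fell, with 333 at an unadjusted p of 0.05 (447 for independent libraries), and with 4 calls by DESeq2 and 5 by voom. With the block 1 rose and 7 fell. The groups did not overlap for 740 genes (8.28%, against 10% for independent libraries). The 1 call was lost without control replicates 1, 2 or 3 of 1.5 h or replicate 3 of 4.0 h, and 3 genes passed without replicate 1 of 4.0 h. The STAT5 and EPO target list lay lower at 4.0 h, with a median of -0.11, a mean of -0.50, 12 of 20 genes lower and 0 called by edgeR in all genes. Adjusted over the list alone 5 fell, and 3 fell with the block (camera adjusted p = 0.00787, adjusted p = 0.405 with an estimated correlation). The immediate early list (median -0.22, 22 of 26 lower, 0 called by edgeR, 2 fallen adjusted over the list alone, camera adjusted p = 0.0589) and the ribosomal protein list (median -0.09, 74 of 78 lower, 0 called in all genes or adjusted over the list alone, camera adjusted p = 0.0912) passed only with the block. There they had adjusted p of 0.0284 and 0.0190, and adjusted p = 0.572 and 0.914 with an estimated correlation.

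The EPO effects at 1.5 h and 4.0 h rest on different libraries, and their calls overlapped. The 5 genes that rose at both times (atf5.2, bcl2l14, ddit3, sdcbp and slc3a2) compare with 0.0190 for independent lists, and the 2 that fell at both (chrna4 and LOC100145554) with 0.00671. With the replicate block 21 genes rose and 15 fell at both times, against 0.311 and 0.226 for independent lists, and 0 went opposite ways. The 21 include atf4 itself, the ER chaperone gene hspa5 and the amino acid transporter genes slc38a2 and slc7a3, and the 15 include azin2, sesn1, cdknx, chrna4 and kcnk2. Across genes, which are not independent replicates, the fold changes at both times had a covariance of 0.105, against a mean of 0.00114 (from -0.00190 to 0.00427) in 10 simulations of unchanged groups. The simulations hold no difference between EPO and control that varies with the replicate number. Both times may share such differences, so the overlap and the covariance are not agreement of independent samples.

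The culture effect and the EPO effect at 1.5 h share the control libraries with opposite signs. With the replicate block 27 genes rose in both, against 0.677 for independent lists, 6 fell in both, against 0.260, and 0 went opposite ways. Among the 27 were cish, socs1, myc, atf4, slc3a2, slc38a2, hsp90ab1, hspa5, bcl2l10, ubb and rnf227, so that these rose in culture and rose further with EPO. Without the block rnf227 and bcl2l14 rose in both. The covariance of the fold changes was -0.0540, against -0.127 (from -0.138 to -0.119) in the simulations, and the 3 control libraries are too few to be split. Culture for 1.5 h and 4.0 h share the fresh libraries, and with the block 24 genes rose and 16 fell in both, against 0.226 and 0.127 for independent lists. Part of that overlap may come from the shared fresh libraries, and the simulations of unchanged groups did not cover this pair of comparisons.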

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

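The 12 genes below were chosen after their values were seen, except that cish was named beforehand for every comparison. In the fit with the replicate number as a block, 12 genes had an EPO effect that differed between 4.0 h and 1.5 h, by the edgeR test of the difference itself. By the same test of all libraries without the block, adjusted p lay between 0.371 and 1.00. Over 22 alternatives, the block included, cish passed in 5, rasl11b in 3, bcl2l10, ldlrad4, lima1, sgk1 and txnip in 2, and the other 5 genes in the block alone. Groups of 3 libraries are too small for a test of single outlying libraries.

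Of the 12, 11 had a lower signed log2 fold change with EPO at 4.0 h than at 1.5 h, and 2 of these (sgk1 and rasl11b) went from above 0 to further below it. Differences in log2 fold change, with effects at 1.5 h and 4.0 h after them, were -2.60 for cish (1.95 and -0.66, adjusted p = 0.00490), -2.49 for the kinase gene sgk1 (0.88 and -1.60, adjusted p = 0.0282), -1.58 for lima1 (1.82 and 0.25, adjusted p = 0.0127), -1.54 for ldlrad4 (1.45 and -0.10, adjusted p = 0.00772) and -1.53 for bcl2l10 of the BCL2 family (1.78 and 0.25, adjusted p = 4.25e-06). The others were -1.42 for rasl11b (0.42 and -1.0, adjusted p = 5.66e-05), -1.14 for LOC100486918 (2.49 and 1.36, adjusted p = 0.00194), -0.95 for maff (1.29 and 0.34, adjusted p = 0.0265), -0.94 for the ceramidase gene acer2 (1.20 and 0.26, adjusted p = 0.0156), -0.94 for the adenosine receptor gene adora2a (1.39 and 0.45, adjusted p = 0.00553) and -0.74 for the ubiquitin gene ubb (0.62 and -0.12, adjusted p = 5.66e-05). The thioredoxin inhibitor gene txnip went the other way by 1.71 (-1.11 and 0.59, adjusted p = 0.0321). Across 7 variants of the blocked fit, cish, bcl2l10, ubb and sgk1 passed in 7, rasl11b in 6, LOC100486918, ldlrad4 and txnip in 5, adora2a and acer2 in 4, and lima1 and maff in 3.

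The gene cish rose with EPO at 1.5 h and not at 4.0 h, where it lay at 16 ± 2.40 CPM with EPO and 25.8 ± 11.8 CPM in control (SD, n = 3). Exchanged labels of EPO and control libraries at 4.0 h would turn the ATF4 response list below 0 in at least 1 replicate number there. That holds if EPO raises the list at 4.0 h, as it did at 1.5 h. Its median differences were 0.47, 0.16 and 0.54 in numbers 1, 2 and 3. The tables argue against an exchange in numbers 1 and 3. The value of number 2 is small and has no error, so it does not decide. The difference between the times had an adjusted p of 0.00490 with the block (at most 0.0293 in 7 variants of the blocked fit). Without the block it was -2.59 ± 0.529 with an unadjusted p of 3.22e-04, and over all genes its adjusted p was 0.813 (1.02e-10 to 1.00 over 22 alternatives), so the call depends on the fit. A short-lived response to EPO may remain, as a hypothesis, and loss of EPO from the medium, which would look alike, was not tested.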

How the results depend on the processing

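Thinning, the variants of the blocked fit and leaving out the 3 libraries that stood apart were chosen after the data were seen, and the other alternatives before. Depth limits the calls, since fresh libraries hold as few as 1329340 counts and thinning every library to that total left 50 of the 85 named calls. Over all alternatives the 85 named calls gave 1601 values, of which 1230 kept the call, 371 lost it and 0 changed direction. Calls kept were 81 of 85 with DESeq2 size factors, 84 without globin genes, 84 with DESeq2, 83 without a filter, 70 with voom, 73 of 74 at 10 CPM, 71 of 84 with only the groups compared, 67 at 2-fold and 56 without the 3 libraries that stood apart. Unless said, the cause of a change was not tested.

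Without a block the comparisons called 39 (EPO at 1.5 h), 17 (EPO at 4.0 h), 106 (mean), 0 (difference of the EPO effects), 29 (culture 1.5 h), 6 (culture 4.0 h) and 1 (culture 4.0 h against 1.5 h) genes. DESeq2 called 71, 42, 193, 54, 13 and 4 (EPO at 1.5 h, at 4.0 h and mean, culture 1.5 h, 4.0 h and 4.0 h against 1.5 h), and voom 70 and 27 for EPO at 1.5 h and 4.0 h, 2 for the difference, and 18, 2 and 5 for culture. Without a filter on low counts, which changes the genes tested, there were 66, 37, 163, 7, 68, 38 and 7, with 116 of the 163 higher against 58 of the 106. At 10 CPM EPO at 4.0 h had 26 and culture 4.0 h had 3. With only the groups compared the difference had 1 and culture 4.0 h against 1.5 h had 5. A 2-fold minimum, which removes smaller changes by construction, left 10 for EPO at 4.0 h and 40 for the mean. Thinned libraries gave 7 for EPO at 4.0 h and 2 for culture 4.0 h against 1.5 h. Without the 3 libraries that stood apart there were 4 for EPO at 4.0 h, 2 for the difference and 3 for culture 4.0 h against 1.5 h. Of 147 list results 15 passed, 2 with an estimated correlation, 5 with fry in one direction and 31 with fry in mixed directions.

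Leaving out 1 library at a time, which leaves 2 in its group, gave 13 to 36 calls for EPO at 1.5 h, 0 to 12 at 4.0 h, 66 to 111 for the mean, 7 to 29 for culture 1.5 h, 0 to 11 for culture 4.0 h and 0 to 3 for culture 4.0 h against 1.5 h. Direction changed only for genes that were not called. For EPO at 1.5 h, tfrc (-0.12) was 0.0157 with voom and -0.51 to 0.16 with 1 library left out, bcl2l1 (-0.04) was -0.112 to 0.0491, and alas2 (-0.05) was -0.122 to 0.0128. For EPO at 4.0 h, socs1 (0.07) was -0.12 without the 3 libraries that stood apart and -0.67 to 1.33 with 1 library left out.

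The replicate block raised the counts to 139, 76, 330, 12, 117, 53 and 8, and list results from 15 to 22. Beyond the genes and lists named with their blocked values, the block changed no call of a named gene or list. Leaving out 1 replicate number in the blocked fit gave 69 to 75 calls for EPO at 1.5 h, 37 to 60 at 4.0 h, 140 to 188 for the mean, 6 to 9 for the difference, 48 to 105 for culture 1.5 h, 22 to 50 for culture 4.0 h and 5 to 16 for culture 4.0 h against 1.5 h, which also had 16 with the block and thinned libraries. The simulated data gave 5 false calls with the block and 0 without. With the block 32% of the 2-fold and 72% of the 4-fold changes were recovered, and 14% and 61% without.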

Other observations

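Tests chosen after the result was seen are those of granulocytes and monocytes, of thrombocytes, of lymphocytes and of bacterial material for the ATF4 response, and the genes of replicate numbers below were chosen after their values were seen. With the replicate block, 21 genes rose with EPO at both times, and no test of enrichment was run on them. They include the transcription factor genes atf4, ddit3 and atf5.2, the amino acid transporter genes slc3a2, slc38a2 and slc7a3, and the chaperone genes hspa5, hspa1b and hsp90ab1, while azin2, sesn1, cdknx, chrna4 and kcnk2 are among the 15 that fell at both times. The ATF4 response was higher with EPO in each replicate number, by medians of 0.91, 0.38 and 0.76 (log2) at 1.5 h and 0.47, 0.16 and 0.54 at 4.0 h.

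The deeper sequencing of the EPO libraries was tested by a single random thinning of every library to the same total. It left a median of 0.49 over 22 measured list members, against 0.52 over all 26 before thinning. The medians cover different sets of genes, but the rise remained at equal totals. Thinning keeps each gene's expected share of the counts, so it cannot remove what else may differ with depth. The tables therefore argue only against unequal totals in themselves as the cause. More granulocytes, monocytes or thrombocytes in the EPO libraries would raise their own genes at least as much. The granulocyte and monocyte list had a median of 0.0857 (95% bootstrap interval over its 20 members -0.16 to 0.35) and the thrombocyte list of -0.00352 (-0.33 to 0.11). Both lists as a whole lay below 0.52 in these libraries. The intervals resample genes, which may move together, and not libraries. They do not measure how the share of these cells varies between samples, so they do not exclude such a change. More lymphocytes stay open, since 4 T and NK cell genes and 2 B cell genes were measured (median -0.28, from -0.72 to 0.37). Bacterial material carried over with the EPO made in E. coli stays open, since the NF-kB and inflammatory list had a median of 0.19 (-0.11 to 0.54), and no group received a mock preparation. An ATF4 response to EPO itself in blood cells may be a hypothesis, and an effect of the preparation cannot be told apart from it.

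Thrombocyte genes lay lower in both control cultures than in fresh cells, by a median of -0.67 in the mean of both times with the block. Without the block the list passed camera at each time with the preset correlation but not with an estimated one, so its fall as a set depends on that setting. In thinned libraries the median was -0.76 (8 measured members, 13 before thinning), so the fall remained at equal totals. Thinning keeps each gene's expected share of the counts. The filter on low counts was rerun, which can favour members that are high in fresh cells. Shallow sequencing of the fresh libraries therefore stays open. Loss of thrombocytes from the suspension, which would lower their most abundant genes, could account for part of the fall. The 5 with the highest level in fresh cells belong to the same list and were picked by the fresh libraries, which can favour a fall. They therefore give no separate support. Their median was -0.43, that of itga2b.1 (± 0.256, SE), but they differed. The gene tubb1 (354 CPM in fresh cells) had 0.10 ± 0.0787, plek -0.32 ± 0.284, fermt3 -1.83 ± 0.428 and itgb3 -2.58 ± 0.412. Unequal turnover of transcripts, or tubb1 made by erythrocytes, may also give this picture and was not tested. None of the 13 thrombocyte genes is in another list. Granulocyte and monocyte genes lay lower in the same comparison, by a median of -0.49 with 16 of 20 lower (cybb -1.71 ± 0.404, edgeR adjusted p = 0.0114 with the block and 0.0851 without). Whether that list fell as a set in the mean of both times was not tested. By camera it passed at 1.5 h but not at 4.0 h, and not with an estimated correlation.

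The replicate numbers differed in 620 of 8939 genes (edgeR quasi-likelihood F test in the blocked fit), with 5 libraries per number. The ferritin gene fth1.1 lay at 21717 ± 441, 21610 ± 815 and 32202 ± 925 CPM in the libraries of numbers 1, 2 and 3 (SD), the globin gene hba2 at 657 ± 39.0, 228 ± 8.63 and 378 ± 70.0 CPM, the autophagy kinase gene ulk2 at 28.9 ± 6.45, 82.5 ± 13.7 and 173 ± 62.0 CPM, and the thioredoxin gene txn at 52.4 ± 18.3, 25.4 ± 7.08 and 12.9 ± 3.32 CPM. The labels do not say what the numbers share.

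Regrouping the libraries tested each count of calls. For the mean EPO effect 1 of 100 splits, the real one, reached 106 calls and the highest other gave 26. With the replicate block 1 of 32 reached 330 and the highest other gave 34. These splits exchange libraries at 1.5 h and 4.0 h separately, as if both times of a replicate number were independent. With the 3 numbers as units there would be too few splits for a share under 0.05, so chance is not excluded. For the difference of the EPO effects there were 0 calls, a count that 100 of 100 splits reach by construction, so the splits say nothing about chance there. The split with the highest count (106) exchanges EPO and control at 1 time, which turns the difference into the mean effect and points to that structure of the samples. For the other comparisons 3 against 3 libraries make 10 splits, too few for a share under 0.05. In each, 1 split, the real one, gave the real count, and the highest others were 0 against 39 for EPO at 1.5 h, 0 against 17 at 4.0 h, 1 against 29 for culture 1.5 h, 0 against 6 for culture 4.0 h and 0 against 1 for culture 4.0 h against 1.5 h. Among the 4 splits of each that part all 3 pairs, which include the real one, the highest other was 0, and the remaining 6 keep a pair together.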
